A study of Mus musculus with 6 samples.

How the data were processed

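PolyA RNA from sorted large peritoneal macrophages of E. coli-infected mice was measured in 6 libraries, 3 from floxed control and 3 from PAC knockout mice, grouped by the genotype and treatment labels. Per the labels' protocols, libraries were made with an NEBNext Ultra II RNA kit and sequenced on a NovaSeq instrument. Reads were aligned with HISAT2 2.0.5 to GRCm38 and counted per gene with featureCounts 1.5.0-p3, per the submitters' processing notes. The annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and near-identical copies may share reads.

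The deposited table holds 20336 genes, and its smallest total per gene was 2 counts. It gives raw counts per gene and library, which were the values tested. It also gives a normalised signal, which the authors made by dividing the count by a size factor per library (0.901 to 1.10, as found from the values), and the mean signal per group. FPKM values in the authors' table were computed from gene length and read count, per the labels' protocols; their denominators, found from the values, lie below the count totals. The log2 fold changes, p-values and adjusted p-values in the deposited table are the authors' own; the tool behind them is not given in the sources used here, and the adjustment covers 10871 genes. Only the counts entered the tests. The number of columns of other samples was 0, so none is left out.

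Depth was 15981530 to 20648832 counts per library. A gene with 0 counts in a library could be present at up to 0.145 to 0.188 CPM (3 counts), and such floors cover counting error only. No library pair was within sampling noise of another: the chi-square per gene was at least 25.0.

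Genes were kept by edgeR's default expression filter, which left 12786, and scaled by TMM. The test was edgeR 4.0.16's robust quasi-likelihood test in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change was derived from its F statistic. CPM values use TMM-scaled totals of the tested genes. Gene lists were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry; lists needed 5 tested members. Before the data were examined, 40 lists, of which 3 were checks of the labels, and the design, the alternatives and the rule for named genes were fixed.

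The rule named the targeted gene and Cx3cr1. It named up to 12 called genes per direction among protein-coding genes of average log2 CPM of at least 1 whose groups did not overlap and whose symbol is not a Gm number, Rik or accession name, and, with fewer than 5 called, up to 5 genes of smallest p in that direction, said not to pass. It named up to 4 members of smallest p of each called list and at most 2 of each other list. The rule yielded more genes than the text prints; Loxl2 was chosen after its values were seen. The result of 1 list that was not called and the values of 1 named gene are not reported here.

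The alternatives fixed beforehand were DESeq2-type size factors, library totals only, no filter, a stricter filter, DESeq2 1.42.0, limma-voom with quality weights, a replicate block, each library left out, a threshold of 0.1, and, for lists, an estimated correlation. Added after seeing the data were edgeR without a robust prior, edgeR's likelihood ratio test, the B cell score as a covariate, and leaving out the library of each group richest in B cell RNA.

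The test was tested on simulated data for this comparison, with the real means, totals and dispersions of 12786 genes. In them 100 genes were changed per fold size, drawn only from genes of average log2 CPM above 2. The interferon response list was raised in the same run. The test recovered 59% of 2-fold and 92% of 4-fold changes among the drawn genes, with 6 false calls. This recovery need not hold for genes of lower counts or where fewer genes change. With no simulated change the test called 1 gene and 0 lists. The simulated genes varied independently of each other, so the 0 says nothing about lists whose genes move together.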

Results

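Large peritoneal macrophages, the main resident macrophage of the mouse peritoneal cavity, were profiled by polyA RNA sequencing 30 min after intraperitoneal injection of E. coli. The cells were sorted by surface staining from mice that carried a floxed PAC gene (floxed control, 3 libraries) and from mice in which PAC was deleted conditionally (PAC knockout, 3 libraries). PAC is the proton-activated chloride channel, and its gene (now Pacc1) is listed under its older name, Tmem206. The genotype label of the knockout names Cxcr3, whereas the design text names Cx3cr1, as the driver of the deletion. Libraries from mice given PBS are mentioned in the design text and were not analysed here, so no comparison with uninfected cells was made. Total counts ranged from 15981530 to 20648832 per library. The labels do not say whether each library came from a separate mouse, so p-values measure only the spread between these libraries, which may be technical.

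The comparison of the 2 genotypes addresses how the transcriptome of infected peritoneal macrophages differs between PAC knockout and floxed control. A driver is named above for the knockout only, so effects of a driver allele cannot be told apart here from those of channel loss. Tmem206 itself (ENSMUSG00000026627, GRCm38 chromosome 1, 191325912 to 191350914, plus strand) averaged 8.91 ± 3.02 normalised counts (CPM, scaled to library size; SD, n = 3) in the floxed control and 5.30 ± 0.946 CPM (SD, n = 3) in the knockout, 59.5% of the control level. The 3 knockout libraries held 4.27 to 6.13 CPM and the 3 control libraries 6.33 to 12.2 CPM, without overlap. The log2 fold change was -0.75 with a standard error (SE) of 0.31. A two-sided exact permutation test gave p = 0.10, the smallest p that 3 libraries against 3 allow. The edgeR adjusted p over all genes was 0.997. Without floxed control replicate 2 the log2 fold change was -0.45. The counts cover the whole gene, and the labels do not say which exons were floxed, so they do not measure the deleted part alone. How completely the gene was deleted in these cells cannot be told from these values. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879, minus strand), a chemokine receptor gene, had 18, 12 and 8 counts in the control libraries and 8, 0 and 0 in the knockout libraries, too few for the test.

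**Figure D1:**
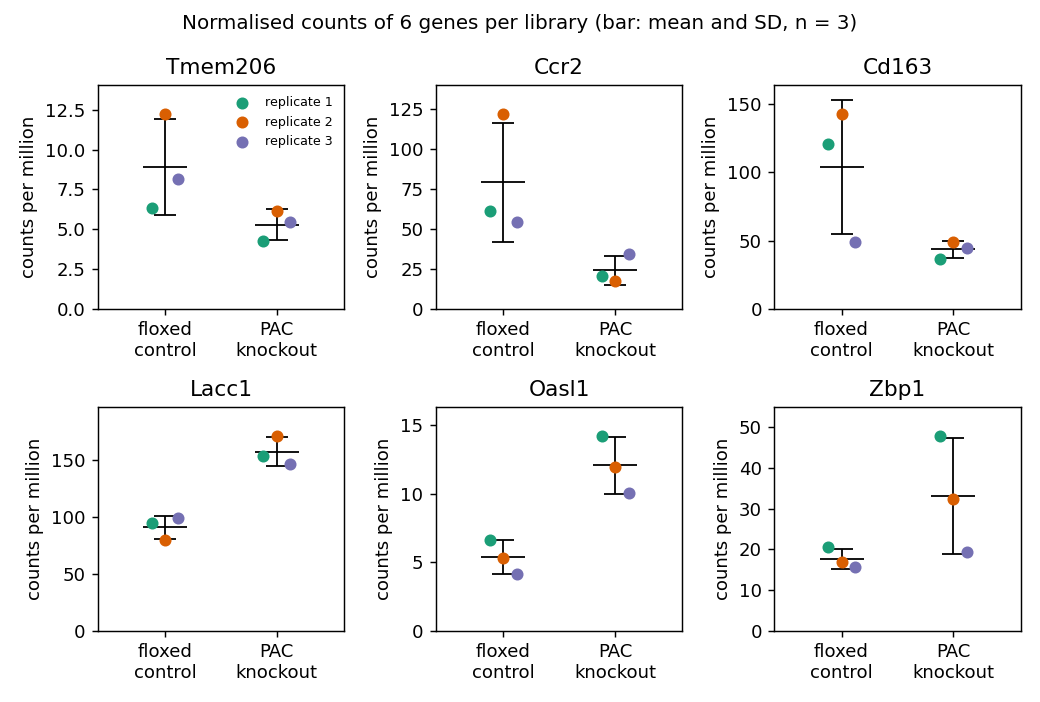
Normalised counts (CPM, linear axis from 0) of 6 genes in each library, by genotype; points are libraries coloured by replicate number, and bars show the mean and SD (n = 3). The Tmem206 points of the knockout lie between 4.27 and 6.13 CPM and those of the control between 6.33 and 12.2 CPM.

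Of single genes, 0 passed the test in either direction. Among 12786 genes tested with edgeR's quasi-likelihood test, the smallest adjusted p was 0.997. At an unadjusted p under 0.05 there were 534 genes, 267 with higher and 267 with lower values in the knockout, where 639 would be reached by chance. The groups did not overlap for 1193 genes, or 9.33%, where chance gives 10%. DESeq2 called 22 genes on the same counts, 11 higher and 11 lower, and limma-voom called 0. With no filter on low counts, edgeR called 20 genes higher and 18 lower. Of these 38 genes only 1 lay outside the 12786 genes tested with the filter. Without floxed control replicate 3, edgeR called 8 genes higher and 10 lower. Without knockout replicate 1 it called 5 higher, and without floxed control replicate 1 it called 2 lower.

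The 5 genes of smallest p-value in each direction are given as values, since none passed the adjusted threshold; they were drawn from protein-coding genes with an average log2 CPM of at least 1, groups that did not overlap and a symbol other than a Gm number, Rik or accession name. On the higher side, Lacc1, an enzyme of macrophage purine metabolism (chromosome 14, 77024200 to 77036904), averaged 90.7 ± 9.98 CPM in the control and 157 ± 12.6 CPM in the knockout (SD, n = 3), a log2 fold change of 0.79 (SE 0.13). The ribosomal protein gene Rpl41 had a log2 fold change of 0.79 (SE 0.15) and Nxpe5 of 0.64 (SE 0.14). Psme2b, a near copy of the proteasome activator gene Psme2 with which it may share reads, stood at 1.07 (SE 0.23), and the ATP synthase subunit gene Atp5g1 at 0.96 (SE 0.21). On the lower side, Pdgfb, a growth factor gene, averaged 11.4 ± 3.47 CPM in the control and 2.82 ± 1.84 CPM in the knockout (SD, n = 3), a log2 fold change of -2.00 (SE 0.44). Plekho1 stood at -1.51 (SE 0.35), the cytokine signalling suppressor Socs6 at -0.94 (SE 0.19), the sphingosine-1-phosphate receptor S1pr5 at -0.84 (SE 0.19), and the AP-1 subunit Jund at -0.72 (SE 0.18). Their unadjusted edgeR p-values ran from 9.8e-05 for Lacc1 to 0.00174 for Jund. All of these genes were among those that edgeR called with no filter on low counts.

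The authors' deposited table of the same comparison holds 22 genes with an adjusted p under 0.05, 9 higher and 13 lower in the knockout. It gives Ccr2 a log2 fold change of -1.72 and an adjusted p of 4.66e-05, and Lacc1 0.79 and 0.00172, in the authors' deposited table. In 6 of the 22 genes the libraries of a single group spanned more than 2 log2 units, and 5 of the 22 are pseudogenes. These features of the authors' deposited table were examined after its values were seen. Loxl2, for example, a lysyl oxidase gene, had 5550, 6464 and 565 counts in the 3 control libraries and 229 to 307 counts in the knockout libraries.

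Genes of the type I interferon response had higher values in the knockout. Of 35 tested members, 34 had higher and 1 had lower values in the knockout, with a median log2 fold change of 0.49. Camera with a preset correlation of 0.01 called the list higher (adjusted p = 5.22e-15), and with an estimated correlation it did not (adjusted p = 0.650). Oasl1, a 2'-5'-oligoadenylate synthetase-like gene, averaged 5.38 ± 1.24 CPM in the control and 12.1 ± 2.10 CPM in the knockout (SD, n = 3), a log2 fold change of 1.16 (SE 0.27). The nucleic acid sensor Zbp1 had 0.91 (SE 0.29) and the ISG15 protease Usp18 0.95 (SE 0.35). No member passed over all genes tested, and 1 passed when adjusted over the list alone. The list's score was 0.55, 0.31 and -0.18 in knockout replicates 1, 2 and 3, and -0.12, -0.24 and -0.28 in the control replicates. Knockout replicate 1 also had the highest scores for mast cell and eosinophil markers (1.85) and for T and NK cell markers (1.03).

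Markers of small peritoneal macrophages and monocytes, and genes of efferocytosis and alternative activation, had lower values in the knockout. Of 19 tested small macrophage and monocyte markers, 14 were lower and 5 higher, with a median log2 fold change of -0.54 (camera adjusted p = 7.16e-06; adjusted p = 0.650 with an estimated correlation). Ccr2, the chemokine receptor of inflammatory monocytes (chromosome 9, 124101950 to 124113557), averaged 79.2 ± 37.1 CPM in the control and 24.1 ± 9.29 CPM in the knockout (SD, n = 3), a log2 fold change of -1.72 (SE 0.40). Cd226 had -1.58 (SE 0.59), Fcrls -1.57 (SE 0.63) and the folate receptor Folr2 -1.25 (SE 0.47). Of 21 tested efferocytosis and alternative activation genes, 17 were lower and 4 higher, with a median of -0.47 (camera adjusted p = 4.20e-07; adjusted p = 0.650 with an estimated correlation). The haemoglobin scavenger receptor Cd163 stood at -1.26 (SE 0.38), the hyaluronan receptor Lyve1 at -1.39 (SE 0.46) and the lectin Clec10a at -0.73 (SE 0.22). The efferocytosis score was 0.36, 0.48 and -0.10 in control replicates 1, 2 and 3, and -0.20, -0.44 and -0.08 in the knockout replicates. Floxed control replicate 3 thus lay within the knockout range. Cd163 likewise had 121, 143 and 48.9 CPM in the control libraries and 36.8, 49.3 and 44.3 CPM in the knockout libraries. For each of these lists 0 members passed over all genes tested and 0 when adjusted over the list alone. The lists overlap, holding 36 tested genes between them. These and the interferon list were called without any 1 library under the preset correlation. The small macrophage median shrank to -0.32 without knockout replicate 2, and the efferocytosis median grew to -0.73 without knockout replicate 2 and to -0.80 without floxed control replicate 3.

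Large peritoneal macrophage identity genes had the opposite direction. Of 29 tested members, 23 had higher and 6 lower values, with a median log2 fold change of 0.17 (camera adjusted p = 0.00145; adjusted p = 0.650 with an estimated correlation). Aspa stood at 0.74 (SE 0.17), Garnl3 at 0.52 (SE 0.18), Naip1 at 0.31 (SE 0.13) and Apoc1 at 1.70 (SE 0.70). No member passed over all genes tested, and 1 passed when adjusted over the list alone. The call was lost without floxed control replicate 2 (median 0.09, adjusted p = 0.0995), and the median was 0.28 without floxed control replicate 3.

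Among lists for the acid compartments in which the channel works, lysosome genes were called higher by a small amount. Of 43 members, 32 had higher and 11 lower values, with a median log2 fold change of 0.08 (camera adjusted p = 0.00502; adjusted p = 0.650 with an estimated correlation). The lysosomal sulfatase Galns had 0.43 (SE 0.14), Naglu 0.37 (SE 0.15), Cd68 0.32 (SE 0.14) and Ctsf 0.33 (SE 0.15). The call was lost without knockout replicate 1 or knockout replicate 2. Vacuolar ATPase genes, the proton pump, were not called (17 members, median -0.04), with Atp6v0a2 at -0.24 (SE 0.16) and Atp6v1e1 at 0.18 (SE 0.14). Chloride channels and transporters were not called (22 members, median -0.08), with Ostm1 at -0.26 (SE 0.12). With 1 library left out, the vacuolar ATPase median ran from -0.06 (without knockout replicate 2) to 0.01 (without knockout replicate 3), and the chloride channel median from -0.17 (without floxed control replicate 3) to -0.04 (without floxed control replicate 1). Nor were phagosome genes and phagocytic receptors (38 members, median -0.0026), NADPH oxidase and reactive oxygen genes (12 members, median 0.02) or autophagy and lysosome biogenesis genes (28 members, median -0.07), of which the last were called lower without knockout replicate 2 (median -0.10, adjusted p = 0.0436).

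Chemokine genes and antigen presentation genes were called higher. Chemokines had 13 of 17 members higher, with a median of 0.22 (camera adjusted p = 0.0137; adjusted p = 0.680 with an estimated correlation). Ccl5 stood at 1.22 (SE 0.39), Cxcl16 at 0.43 (SE 0.19), the interferon-induced Cxcl10 at 0.36 (SE 0.16) and the neutrophil attractant Cxcl1 at -0.37 (SE 0.21). Antigen presentation had 16 of 20 members higher, with a median of 0.20 (camera adjusted p = 0.00592; adjusted p = 0.742 with an estimated correlation), with the peptide transporter Tap1 at 0.53 (SE 0.22) and the immunoproteasome subunit Psmb9 at 0.52 (SE 0.22). The chemokine call was lost without any of 4 of the 6 libraries in turn: knockout replicates 1 and 2 and floxed control replicates 2 and 3. Its median was 0.13 without knockout replicate 3, and 0.56, 0.04 and 0.14 without floxed control replicates 1, 2 and 3. The antigen presentation call was lost without knockout replicate 1 (median 0.07) or floxed control replicate 2, and its median was 0.35 without knockout replicate 2. Cytokine and NF-kappaB target genes were not called (35 members, median 0.08), with Il6 at 0.26 (SE 0.13) and Il1rn at 0.41 (SE 0.19), but were called higher without knockout replicate 1 (median 0.17, adjusted p = 0.00140) or floxed control replicate 1 (median 0.20, adjusted p = 5.68e-05). Toll-like receptor signalling (32 members, median -0.01), inflammasome and pyroptosis (23 members, median 0.08) and immediate early genes (30 members, median -0.07, with Klf4 at -0.44, SE 0.13) were not called either. Immediate early genes were called lower without knockout replicate 2 (median -0.16, camera adjusted p = 0.0300). With 1 library left out, the toll-like receptor median ran from -0.05 (without knockout replicate 1) to 0.03 (without floxed control replicate 1). The inflammasome median ran from -0.0012 (without floxed control replicate 3) to 0.10 (without floxed control replicate 2).

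Cell cycle, ribosomal protein and heat shock genes were called higher. Cell cycle genes had 32 of 35 members higher, with a median of 0.39 (camera adjusted p = 9.08e-07; adjusted p = 0.737 with an estimated correlation), with Tyms at 0.68 (SE 0.22) and Rrm2 at 0.71 (SE 0.27). Cytosolic ribosomal proteins had 38 of 45 members higher, with a median of 0.10 (camera adjusted p = 8.60e-06; adjusted p = 0.803 with an estimated correlation), with Rps21 at 0.56 (SE 0.25). Heat shock and proteostasis genes had 20 of 24 members higher, with a median of 0.14 (camera adjusted p = 0.0137; adjusted p = 0.742 with an estimated correlation), with the endoplasmic reticulum chaperone Hspa5 at 0.40 (SE 0.19). The cell cycle call was lost without knockout replicate 3 (median 0.17), and the median was 0.62 without knockout replicate 2, 0.21 without floxed control replicate 1 and 0.60 without floxed control replicate 3. The ribosomal protein call was lost without floxed control replicate 2 (median 0.02), and the median was 0.20 without floxed control replicate 3. The heat shock call was lost without knockout replicates 1 or 2 (median 0.07 each) or floxed control replicate 2, and the median was 0.30 without knockout replicate 3. The cell cycle score was 0.28, -0.27 and 0.66 in knockout replicates 1, 2 and 3, and -0.56, -0.08 and 0.23 in the control replicates. The ribosomal protein score was 0.08, 0.02 and 0.11 against -0.05, -0.26 and 0.14. The heat shock score was 0.16, 0.23 and -0.18 against 0.02, -0.14 and -0.03. In each of these scores the groups overlapped.

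Markers of other cells that a peritoneal sort can hold varied widely between libraries of the same genotype. Mast cell and eosinophil markers were called higher (8 of 8 members, median 1.28, camera adjusted p = 0.0137, and 0.737 with an estimated correlation). The histamine enzyme Hdc stood at 0.97 (SE 0.38) and the protease Mcpt4 at 1.88 (SE 0.78). Their levels were far apart: Hdc averaged 87.4 CPM in the control and 172 CPM in the knockout. Mcpt4 averaged 0.575 and 2.14 CPM, and Kit 0.359 and 1.08 CPM, both low. T and NK cell markers were called higher (6 of 6 members, median 0.96; camera adjusted p = 0.0155; adjusted p = 0.650 with an estimated correlation), with Il7r at 0.96 (SE 0.61). Both calls were lost without knockout replicate 1, and the T and NK call also without knockout replicate 3 or floxed control replicate 3. The mast cell median turned to -0.25 without knockout replicate 1, and the call was also lost without floxed control replicate 1 (median 0.84). B cell markers were not called, and their median of -0.33 and the camera direction differed in sign (16 members). With 1 library left out they were called higher without knockout replicate 2 (median 0.08) or floxed control replicate 2 (median 1.12) and lower without floxed control replicate 3 (median -0.77). Their score reached 1.92 in floxed control replicate 2 and 1.02 in knockout replicate 1, against -1.55 in floxed control replicate 3. Neutrophil (6 members, median 0.01), dendritic cell (10 members, median -0.24; Irf8 at -0.52, SE 0.15) and mesothelial and stromal markers (6 members, median -0.07, with a camera direction of the other sign) were not called. With 1 library left out, the neutrophil median ran from -0.07 (without knockout replicate 2) to 0.30 (without knockout replicate 3), the dendritic cell median from -0.63 (without floxed control replicate 3) to 0.07 (without knockout replicate 3), and the mesothelial median from -0.18 (without knockout replicate 1) to 0.54 (without knockout replicate 3). Erythroid and platelet markers (4 members, median 1.14) and histone transcripts (3 members, median -0.42) were too few to test.

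**Figure D2:**
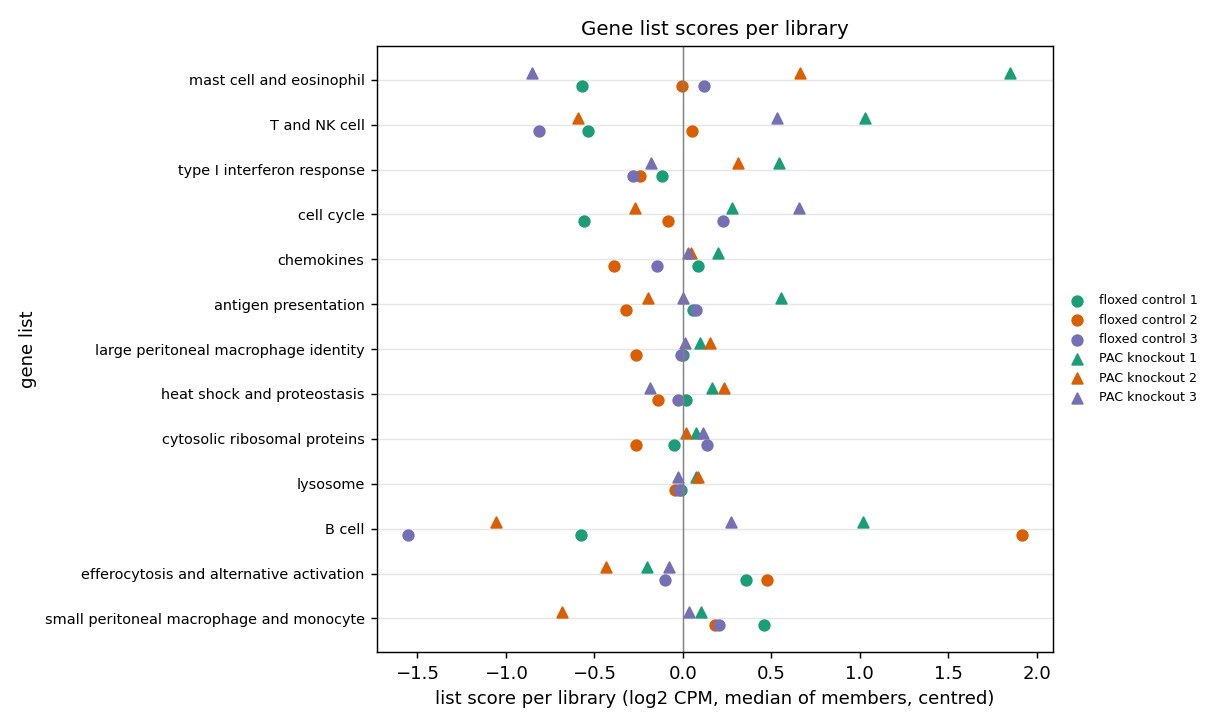
Score of each called gene list, and of the B cell list, in each library: the median over members of log2 CPM after subtracting each gene's mean over the 6 libraries. Circles are floxed control and triangles PAC knockout libraries, coloured by replicate; interferon scores of the knockout run from -0.18 to 0.55 and those of the control from -0.28 to -0.12.

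Metabolic and structural lists were not called with all 6 libraries. Nuclear-encoded oxidative phosphorylation (37 members, median 0.02), mitochondrially encoded genes (12 members, median 0.13), glycolysis and HIF targets (27 members, median 0.04), and cholesterol biosynthesis (23 members, median 0.04) had medians near 0 or slightly above. With 1 library left out, oxidative phosphorylation was called higher without floxed control replicate 3 (median 0.10, adjusted p = 0.00160), mitochondrially encoded genes without knockout replicate 2 (median 0.32, adjusted p = 0.00612) or floxed control replicate 1 (median 0.30, adjusted p = 0.0140), and cholesterol biosynthesis without knockout replicate 2 (median 0.17, adjusted p = 0.0187) or floxed control replicate 3 (median 0.25, adjusted p = 0.0461). Cholesterol efflux and fatty acid genes (25 members, median -0.09) included the apolipoprotein gene Apoe at -0.91 (SE 0.39). NRF2 oxidative stress (21 members, median -0.06), complement and coagulation (28 members, median 0.07), eicosanoid and lipid mediator (19 members, median -0.05) and adhesion and migration genes (34 members, median -0.0014) were not called. With 1 library left out, the NRF2 median ran from -0.14 (without floxed control replicate 2) to 0.07 (without floxed control replicate 1). The complement median ran from -0.003 (without knockout replicate 1) to 0.11 (without floxed control replicate 1). The coagulation factor gene F13a1 averaged 709 ± 308 CPM in the control and 217 ± 132 CPM in the knockout (SD, n = 3), a log2 fold change of -1.71 (SE 0.53). Of sex-linked transcripts, 4 were tested, with a median of -0.0036. In every list other than the interferon and large macrophage identity lists, 0 members passed over all genes tested and 0 when adjusted over the list alone; for Tmem206, a list of its own, the unadjusted edgeR p-value was 0.0367. In all, 12 of 35 lists tested were called with the preset correlation, 0 with an estimated correlation and 0 by fry.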

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

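The edgeR counts of 0 genes higher and 0 lower held with other size factors, library totals, the stricter filter, limma-voom, the threshold of 0.1 and, added after seeing the data, without a robust prior and with the B cell score as covariate. Without a filter on low counts 20 genes were higher and 18 lower, DESeq2 called 11 and 11, and the added likelihood ratio test called 6 and 2; the cause was not tested. DESeq2 shared 18 of its 22 genes with the authors' deposited table. Leaving out 1 library gave 0 to 8 genes higher and 0 to 10 lower, the most without floxed control replicate 3. Leaving out the library of each group richest in B cell RNA, also added, gave 4 higher and 0 lower. The 12 called lists became 0 with an estimated correlation, 10 with the stricter filter (which left the T and NK cell and mast cell lists too few members to test), 7 to 14 with 1 library left out (7 without knockout replicate 1) and 6 without the libraries richest in B cell RNA; fewer samples entered these fits. PAC kept its sign and did not pass in any alternative; its log2 fold change was -0.32 without the libraries richest in B cell RNA. The B cell list turned to a called decrease without floxed control replicate 3 (median -0.77) and to a called increase without floxed control replicate 2 (median 1.12, adjusted p = 6.45e-08) or knockout replicate 2 (median 0.08, adjusted p = 0.0187), and its median ran from -1.004 to 1.12 with 1 library left out. The mast cell median turned to -0.25 without knockout replicate 1. Without the libraries richest in B cell RNA, antigen presentation lost its call and its direction (median 0.0018), and mitochondrially encoded genes were called lower (median -0.30), whereas they were called higher without knockout replicate 2 (median 0.32) or floxed control replicate 1 (median 0.30); the cause was not tested. Of 1728 pairs of a named gene and an alternative, 7 changed sign, all uncalled, and 30 were newly called. As a set, the replicate numbers showed no pairing of the libraries. After each group's mean was subtracted, same-numbered libraries correlated at -0.048, -0.061 and 0.085, and differently numbered ones at up to 0.107. Knockout replicate 3 and floxed control replicate 3 had the lowest chi-square per gene of all library pairs. The column headers number these libraries consecutively and after all the others, and what the numbers stand for is not given. A link between these libraries was not tested and stays open. It could bear on results in which floxed control replicate 3 lay near the knockout libraries. With the replicate block 0 genes were higher, 0 lower and 12 lists called. Depth limits transcripts near the floor of 0.145 to 0.188 CPM. The simulated recovery of 59% of 2-fold changes covered only genes of average log2 CPM above 2 and was not split by depth.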

Other observations

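Of the tests below, those of B cell RNA, of class II genes, of the Cx3cr1 region, of switched transcripts, of clock and glucocorticoid genes and of the splits for the interferon list were chosen after the result was seen; the single-library test and the splits for counts of genes and lists were set before it.

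A set of transcripts was low in some libraries and much higher in others of the same genotype. With a gap of at least 2 log2 units between libraries and at least 100 counts in 1 library, 23 of 9803 genes switched within a genotype, 10 of them pseudogenes, and 6 are among the 22 calls of the authors' deposited table. Gm14085 (chromosome 2, 122484941 to 122528040) had 9, 195 and 206 counts in the control libraries and 2 in each knockout library, and its neighbour Gatm (122594467 to 122611303) had 58, 338 and 396 against 55 to 77. On chromosome 7, Lilra6 had 414, 831 and 428 counts in knockout replicates 2 and 3 and floxed control replicate 3 and at most 29 elsewhere, while Eps8l1 had 16, 3 and 5 in those libraries and at least 159 in the others.

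Inherited variants that differ between animals are a candidate explanation for the switched transcripts. Of 6 pairs of switched genes within 1 Mb, 2 had the same pattern of libraries, against a mean of 0.294 in 2000 shuffles (permutation p = 0.0265). A first version that also counted opposite patterns, such as those of Lilra6 and Eps8l1, found 4 pairs, against a mean of 0.342 (permutation p = 0.0015). The 2 pairs are Gm14085 with Gatm and Lilra6 with a nearby pseudogene. Lilra6 and that pseudogene may share reads, so the explanation rests on few genes. The opposite patterns add Eps8l1 paired with Lilra6 and with the same pseudogene, in the same region of chromosome 7. These pairs are not independent and add no further region. The test was chosen after the genes were seen, so neither permutation p gives the odds of such pairs by chance. For Rps3a2 and Rps3a3, high in knockout replicates 2 and 3 alone, reads of Rps3a1 counted for its copies may account for the values: the sum of the 3 genes varied less than Rps3a1 alone (ratio of coefficients of variation 0.285). Of the switched genes, 0.0435 had a correlation of at least 0.8 in size with the B cell score. That cut is strict for 6 libraries. Gdpd3 and Rps13-ps1, high only in floxed control replicate 2, the library richest in B cell RNA, reached 0.68 and 0.75. B cell RNA stays open for such genes, while Rps3a2, Loxl2 and Gatm had correlations of -0.27, 0.35 and 0.14.

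The genotype, B cell RNA and single libraries were considered as sources of the higher interferon response list. With the B cell score as covariate its median log2 fold change was 0.488 (bootstrap interval over genes 0.412 to 0.701), against 0.489 without. The B cell score averaged 2.74 in the knockout and 2.63 in the control (mean log2 CPM, SD within groups 1.37), so the covariate had little to remove. Floxed control replicate 2, with the highest B cell list score (1.92), had an interferon score of -0.24, and knockout replicate 2 (-1.05) had 0.31. Knockout replicate 1 was high in both (1.02 and 0.55). The order of the libraries thus differed between the B cell and interferon scores, as far as the markers measure B cell RNA. The covariate cannot decide the question, since its groups hardly differed. B cell RNA stays open for knockout replicate 1. Without knockout replicate 1, the highest, the median was 0.332 (interval 0.233 to 0.442), so dependence on that library stays open. Of 10 splits of the 6 libraries, 2, the real one included, gave a camera p as small (real 1.49e-16, smallest other 2.22e-17), and 10 splits are too few for a share under 0.05. The genotype stays open, as untested.

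Lower small macrophage and alternative activation genes may come from fewer small macrophages in the sorted cells, which the surface gate should remove. The class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a median log2 fold change of 0.037 (median SE 0.40), while the 15 other tested markers of the list had a median of -0.85. Since B cells also carry class II RNA and Cd74 averaged 2156 CPM in the control, this cannot be told apart from a change within the cells. Inherited variants near Cx3cr1 acting on nearby genes could reach few lower members: 1 of 27, Ccr2, lay within 5 Mb of it. The lower members lie on 13 chromosomes. Only 68 tested genes lie in that window, so few members of any list would. Effects of such variants on genes elsewhere were not tested and stay open.

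For the counts, splits of the libraries are too few for a share under 0.05. The real split called 0 genes and the highest other 3; a count of 0 is reached by any split, so the 10 of 10 that reached it say nothing about chance. The real split called 12 lists, the lowest other 7 and the highest other 17, and 3 of 10 splits called at least 12.

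The clock gene Nr1d1 had 91, 71 and 851 counts in the knockout libraries and 520, 340 and 655 in the control libraries. Different times of day at collection might produce this, and the spread of 14 clock genes within groups was at percentile 100 of 10000 random lists; a list of 19 glucocorticoid-induced genes also reached 100, so the test is not specific and leaves the question open. A lower glucocorticoid response was a hypothesis from Fkbp5, Zbtb16 and Cd163, and the rest of that list did not bear it out. Over the 16 tested genes that remained, limma's camera gave an adjusted p = 0.593 (Benjamini-Hochberg over 3 added lists, which leaves the raw value as it was).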
